A study of Glycine max with 12 samples.

How the data were processed

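RNA sequencing libraries of soybean (*Glycine max*) leaves were analysed. Old and young leaves came from plants moved, at the fifth leaf stage, to nutrient solution with normal (5 µM) or high (100 µM) manganese, added as the sulfate. The 12 libraries fell into 4 groups of 3, named by leaf age and manganese (Mn) level from the sample labels. A randomized block layout is mentioned in the series description, but the labels do not say whether a replicate number marks a block or which plants a replicate pooled. The p-values therefore measure the spread between these samples, part of which may be technical. The extraction text in the labels speaks of nodule RNA while each sample is labelled as leaf, and the samples were treated here as leaf.

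The authors deposited 1 table of FPKM (fragments per kilobase of gene scaled by the fragment total of the library) for 39811 genes and all 12 libraries. Per the submitters' processing notes, Bowtie2 2.2.3, HISAT2 2.1.0 and DESeq2 1.6.3 were used, with no role or order given. The rule for counting fragments, the treatment of fragments that match near-identical gene copies and the rule by which genes were listed are not given in the sources used here. Values of genes with close copies, which are frequent in soybean, are therefore uncertain, since such fragments could be assigned whole to a copy, counted more than once or left out. Gene IDs in the table end in Wm82.a2.v1. A RefSeq gene table of assembly Glycine_max_v4.0 was searched for the IDs, and 0 of 39811 matched by gene ID, locus tag, symbol, synonym or Ensembl ID. The deposited table does not pair IDs with names, so genes were named by ID, no gene function was assigned, and the pathway and cell type lists fixed beforehand could not be tested. Coordinates were not used here.

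Depth was recovered from the FPKM values. Ratios of FPKM between libraries fell on ratios of whole numbers, from which the fragment total of each library and the length of each gene were solved. All 39811 genes gave fragment numbers within 0.02 of a whole number in all 12 libraries. Recovered totals ran from 17774122 to 21070730 fragments per library, and listed genes held 99.99 to 100.0% of them. On simulated libraries the recovery returned the exact total for 12 of 12 libraries and exact fragment numbers for 99.69% of genes. At these depths 1 fragment in a gene of 1 kb corresponds to an FPKM of 0.0475 to 0.0563.

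Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested, which left 28267. Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of genes with low FPKM. A single linear model with 4 group means was fitted in limma 3.58.1 (R 4.3.3), with moderated variances that followed the trend of expression. The 5 contrasts tested were the Mn response (100 against 5 µM) in old and in young leaves, the difference between these responses (young minus old), and the leaf age difference (young against old) at each Mn level. Adjusted p-values in the text are Benjamini-Hochberg adjusted limma values over the 28267 genes, and a gene was called below an adjusted p of 0.05. Tests were 2-sided. Libraries were also simulated with independent noise and the same spread for a gene in all 4 groups. In these, Mn calls in old leaves covered 57% of genes with a true log2 change of 1 and 94% of those with 2. The shares were 61% and 96% for the Mn response in young leaves. Unchanged genes gave 5 and 8 calls among 28067 in the same simulations. As old leaves at 5 µM varied more than the other groups, these shares and calls do not describe the test in old leaves as observed. Only 100 genes were given each true change in a comparison, far fewer than were called in the data. The adjusted p threshold depends on the share of changed genes, so the simulated shares do not describe the test in young leaves either.

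Genes named by ID were chosen by a rule fixed before the data were examined. Among called genes with a mean FPKM of at least 5 in a compared group and no overlap between the 3 values of each group, the 6 with the strongest rise and the 6 with the strongest fall were taken for each Mn comparison. The same was done for the difference between responses, where no overlap rule applied, and 4 and 4 genes were taken for each leaf age comparison. As no names were paired with the IDs, at most 2 IDs were printed in each direction, and the rest were summarised. Values per group are means ± SD of FPKM with n = 3. Log2 changes carry the standard error (SE) of the moderated model.

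Alternatives fixed before the data were examined were other pseudocounts (0.1 and 5), no filter and a stricter filter (mean FPKM of at least 5), rescaling by median-of-ratios factors, quantile normalization, the replicate number as a term, the 6 compared libraries alone, other variance models, a 2-fold threshold, and leaving out each library in turn. The voom method of limma on the recovered fragments, the overlap of calls between leaf ages and between Mn levels, the grouping of genes by leaf age and the analysis of gene neighbours were added after seeing the data. Set tests on gene lists were not run for the reason given above. The number of calls was also counted under other splits of the libraries. Group means of library measures were compared by exact permutation tests, which with 3 against 3 libraries cannot give a 2-sided p below 0.1. Gene neighbours were tested with 1000 permutations of gene order within chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.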

Results

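Transcript abundance was measured in old and young soybean leaves grown at 5 or 100 µM Mn, with 3 libraries in each of the 4 groups. Mn is an essential micronutrient, needed in the oxygen-evolving complex of photosystem II, and it is toxic in excess. The series asks how leaves of different age respond to high Mn. Libraries held 17774122 to 20526701 fragments in the old-leaf 5 µM group, 18540551 to 20189064 in the old-leaf 100 µM group, 18198700 to 21070730 in the young-leaf 5 µM group and 19608302 to 20826335 in the young-leaf 100 µM group. All 39811 listed genes had a fragment in at least 1 library, and 28267 genes passed the expression filter.

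Leaf age separated the libraries more than Mn did. The first principal component held 54.5% of the variance and placed the old-leaf libraries between -79.9 and -51.8 and the young-leaf libraries between 46 and 88.9. The second, with 23%, separated the Mn levels in young leaves, where the 5 µM libraries lay between -58.8 and -32.8 and the 100 µM libraries between 59.1 and 61.9. In old leaves the same axis ran from -65.5 to -5.3 at 5 µM and from 10.5 to 26.4 at 100 µM. Replicates correlated at r = 0.974 to 0.986 across genes in the groups other than old leaves at 5 µM, where r was 0.944 to 0.967; genes are not independent replicates. The median SD between replicates was 0.266 on the log2 scale in old leaves at 5 µM and 0.136 to 0.142 in the other groups. Replicate 3 of the old-leaf 5 µM group stood apart on the third component, at -69.3. No pair of replicates agreed within sampling noise, since the chi-square per gene was 8.9 or more in each pair.

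**Figure D1:**
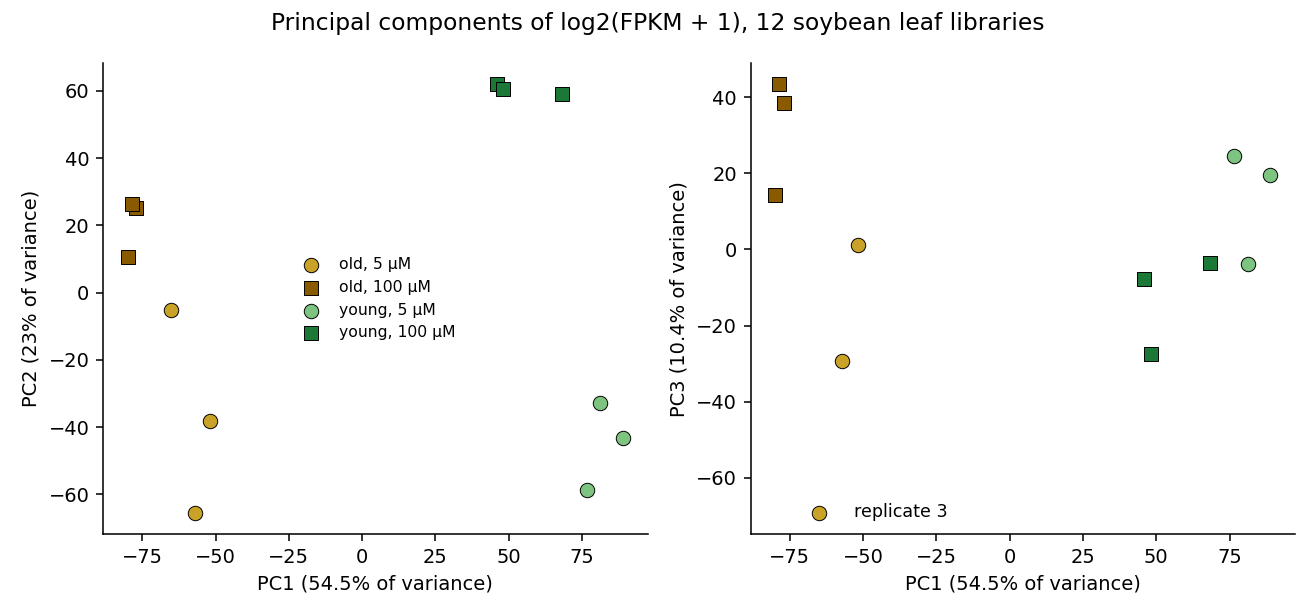
Principal components of log2(FPKM + 1) in 12 leaf libraries, each point 1 library, with the share of variance on each axis (54.5%, 23% and 10.4%). Old leaves lie left and young leaves right, and replicate 3 of the old-leaf 5 µM group lies lowest on the third component.

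The spread of expression over genes also moved with Mn in young leaves. The 20 most abundant genes, a fixed set by mean FPKM over the 12 libraries, were followed. They took 12.6 ± 0.4% of fragments (SD, n = 3) in young leaves at 5 µM and 9.13 ± 0.603% at 100 µM. In the same leaves the median FPKM over genes was 2.38 ± 0.183 at 5 µM and 3.27 ± 0.047 at 100 µM (SD, n = 3). Both differences exceeded the range of the replicates, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. In old leaves the 20 most abundant genes took 7.83 ± 2.23% at 5 µM and 7.83 ± 0.351% at 100 µM (exact permutation p = 1, n = 3). The median FPKM of old leaves was 2.5 ± 0.43 and 2.8 ± 0.0362 (exact permutation p = 0.4, n = 3).

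In the joint model 4551 of 28267 genes were called for Mn in old leaves, of which 3049 rose and 1502 fell at 100 µM. The gene with the strongest rise by the naming rule, Glyma.17G147500.Wm82.a2.v1, went from an FPKM of 0.337 ± 0.146 at 5 µM to 36.8 ± 2.77 at 100 µM (SD, n = 3), a log2 change of 4.82 (SE 0.29, adjusted p = 1.3e-05). Glyma.15G211500.Wm82.a2.v1 rose from 4.48 ± 3.26 to 137 ± 17.1, a log2 change of 4.81 (SE 0.32, adjusted p = 3.1e-05). In the other direction, Glyma.14G116400.Wm82.a2.v1 fell from 129 ± 24.4 to 3.87 ± 3.24, a log2 change of -4.92 (SE 0.45, adjusted p = 0.00012). Glyma.04G069500.Wm82.a2.v1 fell from 91.7 ± 44.4 to 3.55 ± 3.69, a log2 change of -4.54 (SE 0.53, adjusted p = 0.00042). The 6 genes with the strongest rise had log2 changes of 3.24 to 4.82 and the 6 with the strongest fall -4.92 to -3.93, and all 12 were also called in the same direction in young leaves. The deposited table does not pair these IDs with gene names.

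Among genes that changed at least 2-fold in old leaves, falls outnumbered rises, with 830 lower and 667 higher (960 and 515 after median-of-ratios rescaling). The share of calls that were higher, 67%, depended on scaling: it was 50.6% after median-of-ratios rescaling (2234 higher and 2184 lower) and 54.5% after quantile normalization. The count of calls was 7537 (78.8% higher) without replicate 3 of the 5 µM group. It was 2379 without replicate 2 and 2213 without replicate 3 of the 100 µM group. Fitted alone, the 6 old-leaf libraries gave 1038 calls (514 higher and 524 lower), 1026 of them shared with the joint model. That model averages the variance of a gene over the 4 groups, while old leaves at 5 µM varied more (median SD 0.266 against 0.136 to 0.142). Adjusted p-values in old leaves, those of named genes included, are thus likely too small. Fewer degrees of freedom also act on the count of the separate fit.

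In young leaves high Mn changed 9957 genes, with 8379 higher and 1578 lower. Glyma.16G170100.Wm82.a2.v1 rose from an FPKM of 8.83 ± 12.1 to 405 ± 133 (SD, n = 3), a log2 change of 6.11 (SE 0.72, adjusted p = 0.00038); this gene was more abundant in old leaves, at 518 ± 324 and 1830 ± 108, where its log2 change of 2.00 did not pass (adjusted p = 0.083). Glyma.07G243500.Wm82.a2.v1 rose from 17.5 ± 25.3 to 297 ± 148, a log2 change of 4.90 (SE 0.99, adjusted p = 0.0046). At 5 µM replicate 2 lay above the other young-leaf libraries, with 46.8 against 3 and 2.75 for this gene. For Glyma.16G170100.Wm82.a2.v1 the values were 22.8 against 2.56 and 1.15. The same library was the highest of its group at all 6 genes with the strongest rise. Glyma.13G219100.Wm82.a2.v1 fell from 58.2 ± 8.09 to 1.1 ± 0.53, a log2 change of -4.84 (SE 0.43, adjusted p = 9.6e-05), and Glyma.15G093100.Wm82.a2.v1 fell from 145 ± 40.9 to 6.02 ± 3.67, a log2 change of -4.48 (SE 0.47, adjusted p = 0.00021). Both of these also fell in old leaves, with log2 changes of -4.38 and -3.89. The 6 genes with the strongest rise had log2 changes of 4.36 to 6.11, and 1 of them was called higher in old leaves. Of the others, Glyma.07G243500.Wm82.a2.v1 had a log2 change of -0.66 in old leaves. The rest had 0.69 to 2.00 there, none past the threshold. Replicate 3 was the highest old-leaf 5 µM library at each of the 6. The missing calls therefore do not show rises in young leaves alone, though 4 of the 6 were called for the difference between responses. The 6 with the strongest fall ran from -4.84 to -3.81, and all 6 were also called lower in old leaves.

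Rises of at least 2-fold in young leaves numbered 2119 and falls 577, and after median-of-ratios rescaling 1309 and 1061. The median log2 change over all genes was 0.27, and median-of-ratios rescaling brought it to -0.01; under that scaling 3404 genes were higher and 3593 lower, so that the share of higher calls went from 84.2% to 48.6% (47.8% after quantile normalization). The count of calls was 5253 without replicate 3 of the 5 µM group, 6183 and 6213 without replicates 2 and 3 of the 100 µM group, and 5680 when genes were held to a mean FPKM of at least 5. With the 6 young-leaf libraries fitted alone it was 13599 (11267 higher and 2332 lower). The joint model gives both leaf ages the same variance for a gene, though old leaves at 5 µM varied more. The counts for old and young leaves therefore do not compare the size of the responses.

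**Figure D2:**
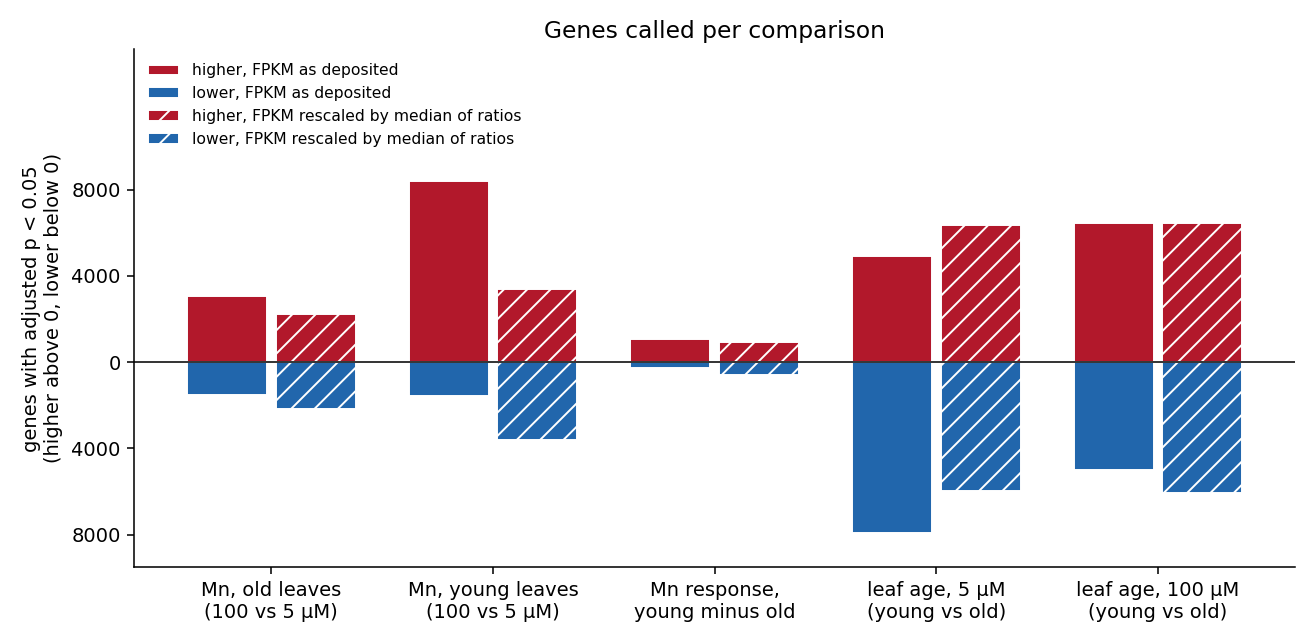
Number of genes with adjusted p below 0.05 in each comparison, higher above 0 and lower below 0. Plain bars are FPKM as deposited and hatched bars FPKM rescaled by median-of-ratios factors; in young leaves the higher calls go from 8379 to 3404 with rescaling and the lower calls from 1578 to 3593.

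The responses of old and young leaves, measured on separate libraries, shared more genes than independent lists would. Of the genes called in both leaf ages, 1520 rose in both, against 903.8 for independent lists, and 685 fell in both, against 83.8. A further 85 were called in opposite directions, so that 96.3% of the 2290 shared calls had the same direction. Across all genes the responses correlated at r = 0.442, with genes not being independent replicates. As the joint model gives both comparisons the same variance for a gene, each leaf age was also fitted on its own 6 libraries, which gave 346 genes higher in both (204.9 for independent lists) and 378 lower in both (43.2). After median-of-ratios rescaling 615 genes rose in both (269 for independent lists) and 1074 fell in both (277.6). Opposite calls numbered 14 in the separate fits and 109 after rescaling. The share in the same direction was 90% without replicate 1 of the old-leaf 5 µM group and 98.1% without replicate 3 of the young-leaf 5 µM group. The 2290 shared calls became 4916 without replicate 3 of the old-leaf 5 µM group, 1322 and 1312 without replicates 2 and 3 of the old-leaf 100 µM group, 1429 without replicate 3 of the young-leaf 5 µM group, 1451 without replicate 2 of the young-leaf 100 µM group, and 1489 at a mean FPKM of at least 5.

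**Figure D3:**
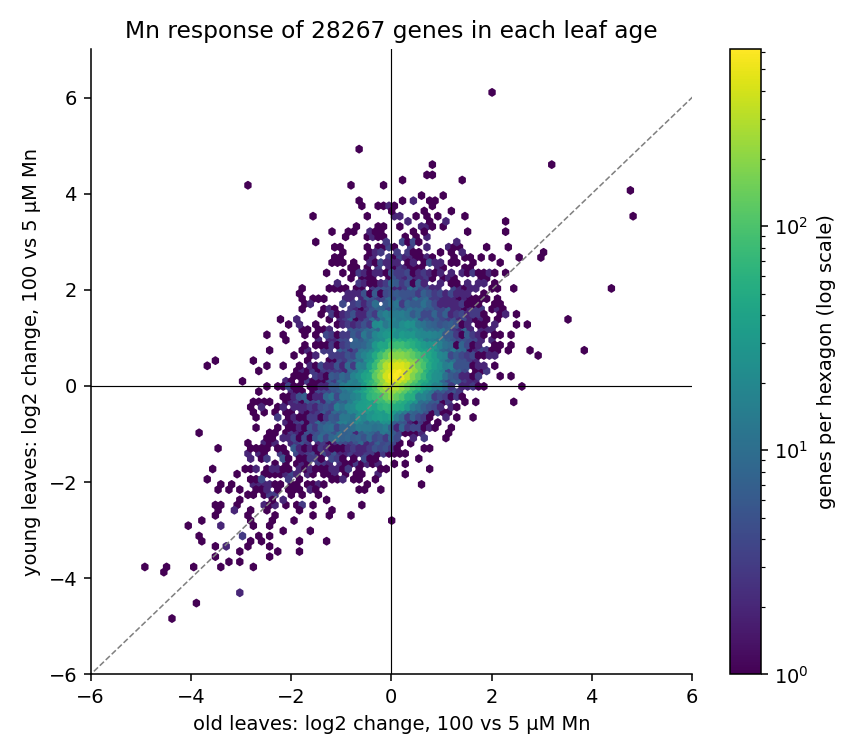
Log2 change at 100 against 5 µM Mn in old leaves (x axis) and young leaves (y axis), as the number of genes per hexagon on a log color scale; the dashed line marks equal responses. Genes called lower in both leaf ages (685) lie at the lower left and genes called lower in old and higher in young leaves (70) at the upper left, and the cloud is centred above 0 on the y axis, at a median of 0.27.

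The Mn response differed between leaf ages for 1320 genes, with 1061 more positive and 259 more negative in young leaves. Glyma.02G083700.Wm82.a2.v1 went in opposite directions: in old leaves its FPKM fell from 98 ± 74.5 to 9.53 ± 3.11 (SD, n = 3; log2 change -2.90), and in young leaves it rose from 0.713 ± 0.588 to 29.2 ± 11.9 (log2 change 4.13), a difference of 7.03 (SE 0.81, adjusted p = 0.0065). For Glyma.07G243500.Wm82.a2.v1 the difference was 5.56 (SE 1.39, adjusted p = 0.047), with a log2 change of -0.66 in old leaves (adjusted p = 0.71). Its values at 5 µM were 161, 85.6 and 733 in the 3 old-leaf libraries and 3, 46.8 and 2.75 in the young-leaf ones. Glyma.15G272800.Wm82.a2.v1 rose more in old leaves, from 3.31 ± 0.523 to 62.9 ± 11.4, than in young leaves, from 6.72 ± 0.999 to 12.5 ± 5.53, a difference of -3.15 (SE 0.34, adjusted p = 0.0052). Glyma.03G036500.Wm82.a2.v1 rose in old leaves from 8.08 ± 2.4 to 48.2 ± 9.63 and stood at 0.632 ± 0.0903 and 0.301 ± 0.0555 in young leaves, a difference of -2.78 (SE 0.27, adjusted p = 0.0052).

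Of the 1061 genes with the more positive response in young leaves, 847 were called higher in young leaves and not called in old leaves, 125 were called lower in old leaves and not called in young leaves, and 70 were called lower in old and higher in young leaves. Of the 259 with the more negative response, 145 were called higher in old leaves and not called in young leaves, 75 were called lower in young leaves and not called in old leaves, and 15 were called higher in old and lower in young leaves. In terms of leaf age, 658 of the 1061 genes were lower in young than in old leaves at 5 µM; 457 of these 658 were not called for leaf age at 100 µM, and 146 were higher in young leaves there. These classes come from the same 12 libraries as the difference itself and are no separate test of it.

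The count of 1320 depended on single libraries. It lay between 194 (without replicate 3 of the young-leaf 100 µM group) and 3232 (without replicate 2 of the old-leaf 5 µM group), with 2516 without replicate 1 of the old-leaf 5 µM group; 823, 290 and 291 without replicates 1, 2 and 3 of the old-leaf 100 µM group; 300 and 210 without replicates 1 and 3 of the young-leaf 5 µM group; and 866 and 660 without replicates 1 and 2 of the young-leaf 100 µM group. The share of higher calls, 80.4%, was 61.8% after median-of-ratios rescaling (950 higher and 586 lower) and 53.6% after quantile normalization, which called 2037 genes; a mean FPKM of at least 5 gave 792 calls and voom on the recovered fragments 823, and 5 of 99 other splits of the libraries, all with the young-leaf Mn groups kept together, gave more calls than 1320. The adjusted p of Glyma.07G243500.Wm82.a2.v1 was 0.07 without replicate 3 of the old-leaf 5 µM group and between 0.051 and 0.12 in each of the 12 settings that did not call it.

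**Figure D4:**
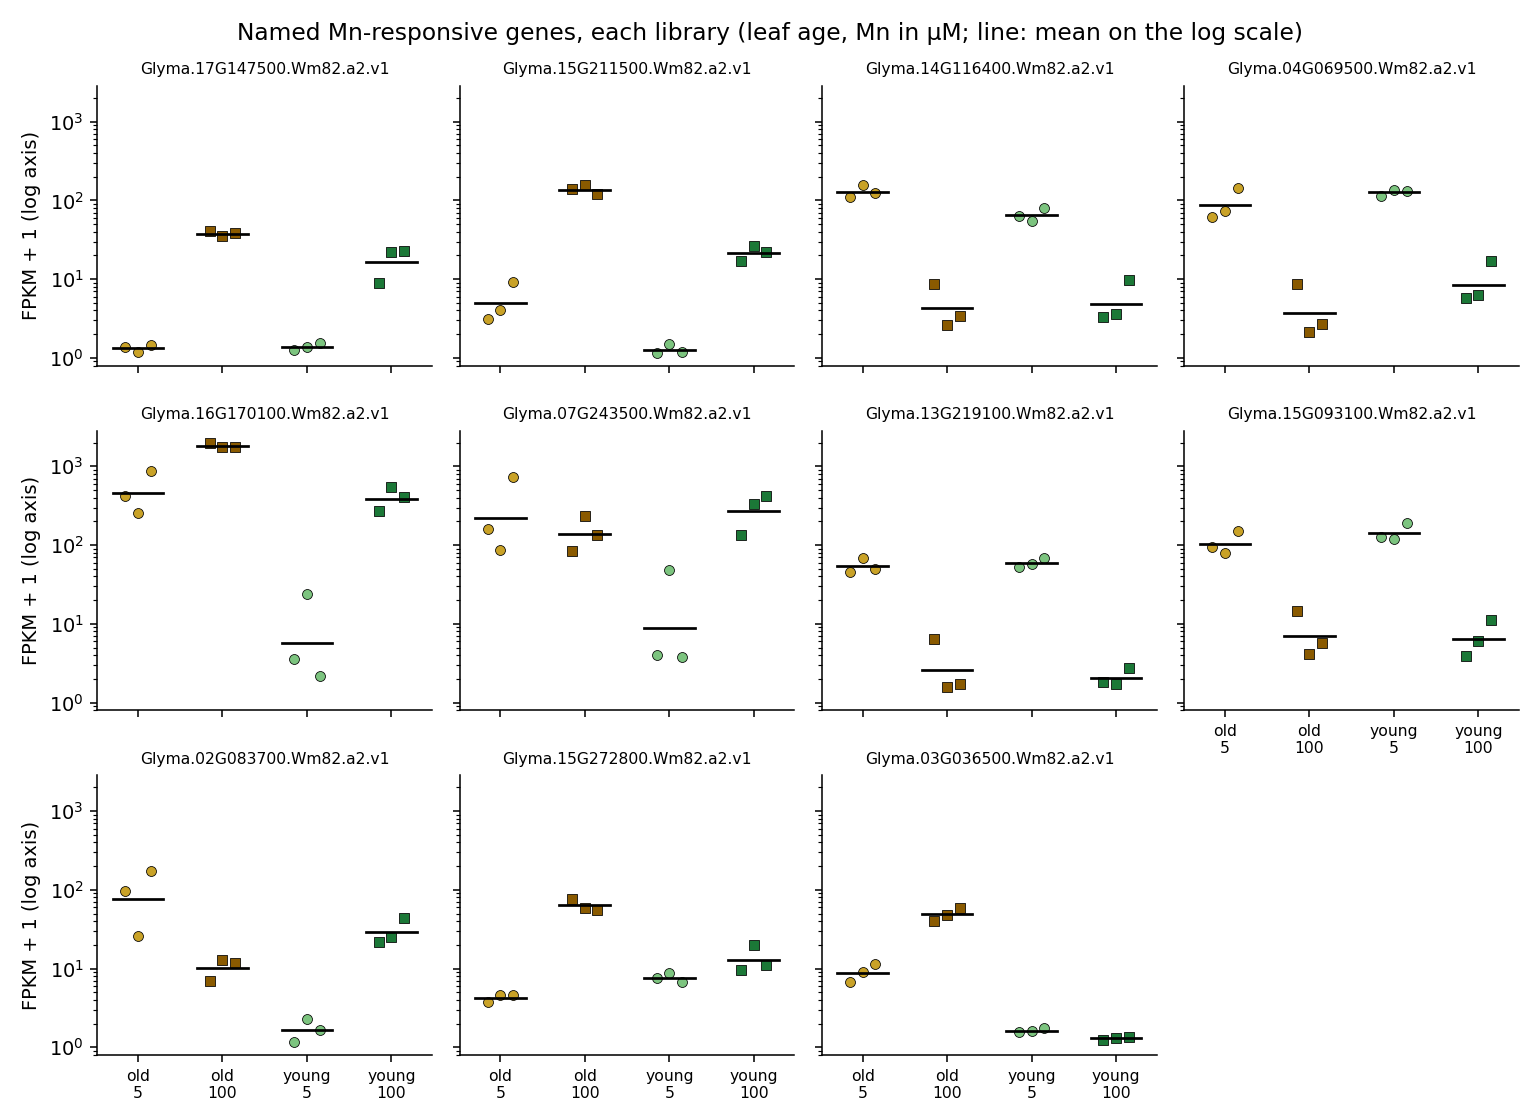
FPKM + 1 on a log axis for the 11 genes named in the Mn comparisons, each point 1 library and each line the mean on the log scale, by leaf age and Mn level in µM. Glyma.02G083700.Wm82.a2.v1 falls with Mn in old leaves and rises in young leaves, while Glyma.13G219100.Wm82.a2.v1 falls in both.

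At 5 µM Mn, 12855 genes differed between leaf ages, 4947 higher and 7908 lower in young leaves. Glyma.11G098400.Wm82.a2.v1 had an FPKM of 1.05 ± 0.574 in old and 1270 ± 96 in young leaves (SD, n = 3), a log2 difference of 9.31 (SE 0.22, adjusted p = 2.9e-10). Glyma.11G098500.Wm82.a2.v1, whose ID follows it on chromosome 11, had 0.771 ± 0.584 and 915 ± 182, a difference of 9.05 (SE 0.27, adjusted p = 2.8e-09). Lower in young leaves were Glyma.14G195000.Wm82.a2.v1, with 790 ± 83.2 in old and 5.46 ± 4.52 in young leaves (log2 difference -7.17, SE 0.44, adjusted p = 6.1e-07), and Glyma.16G170100.Wm82.a2.v1, the gene with the strongest rise with Mn in young leaves, with a difference of -6.33 (SE 0.72, adjusted p = 4.7e-05). Differences of at least 2-fold were found for 2334 higher and 2383 lower genes, and after median-of-ratios rescaling for 2850 and 1915. The share of higher calls, 38.5%, was 51.4% after median-of-ratios rescaling (6340 higher and 5986 lower), and 7506 genes were called at a mean FPKM of at least 5. With the 6 libraries at 5 µM fitted alone, 9343 genes were called, 4032 higher and 5311 lower in young leaves. Old leaves at 5 µM varied more than the joint variance allows, so adjusted p-values of the joint model are likely too small here.

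At 100 µM Mn, 11479 genes differed between leaf ages, 6459 higher and 5020 lower in young leaves. Glyma.14G115500.Wm82.a2.v1 had 1.62 ± 0.447 in old and 2180 ± 168 in young leaves (SD, n = 3), a log2 difference of 9.71 (SE 0.15, adjusted p = 1.2e-11), and Glyma.11G098400.Wm82.a2.v1 again differed, by 9.13 (SE 0.22, adjusted p = 3.8e-10). Glyma.14G195000.Wm82.a2.v1 was lower in young leaves, with a log2 difference of -8.69 (SE 0.44, adjusted p = 1.3e-07), with 687 ± 28.8 in old and 0.823 ± 0.99 in young leaves. Glyma.15G041100.Wm82.a2.v1 stood at 255 ± 88.7 in old and 2.8 ± 0.911 in young leaves, a difference of -6.04 (SE 0.39, adjusted p = 7e-07). Differences of at least 2-fold were found for 3006 higher and 1466 lower genes, and after median-of-ratios rescaling for 2750 and 1571. The share of higher calls, 56.3%, was 44.4% after quantile normalization, and 6087 genes, 2904 higher and 3183 lower, were called at a mean FPKM of at least 5. With the 6 libraries at 100 µM fitted alone, 13980 genes were called, 7912 higher and 6068 lower, more than the 9343 at 5 µM. The order of the counts at the 2 Mn levels thus reversed, and they do not compare the size of the leaf age difference.

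The leaf age differences at the 2 Mn levels, again from separate libraries, shared more genes than independent lists would. Genes higher in young leaves at both levels numbered 3913, against 1130.4 for independent lists, and genes lower at both 3435, against 1404.4. Of the genes called at 5 µM these were 3913 of the 4947 higher and 3435 of the 7908 lower ones. With each Mn level fitted on its own 6 libraries, so that no variance was shared, 3529 genes were higher at both (1128.6 for independent lists) and 3019 lower at both (1140.1). Of the genes called at 5 µM in those fits these were 3529 of 4032 higher and 3019 of 5311 lower ones. The 7908 lower calls at 5 µM were 5986 after median-of-ratios rescaling, so the shares kept depend on scaling and on the variance model. Opposite calls were made for 166 genes, so that 97.8% of the 7514 shared calls had the same direction, and the differences correlated at r = 0.753 across genes, which are not independent replicates.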

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

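The test of the difference between leaf ages was planned, and the other tests in this part were chosen after the results were seen. The Mn response differed between leaf ages for 1320 genes, and 85 genes were called in opposite directions in old and young leaves. The count of opposite calls was 14 with each leaf age fitted on its own 6 libraries. Among the genes whose response differed, the named ones had differences of 7.03 for Glyma.02G083700.Wm82.a2.v1, 5.56 for Glyma.07G243500.Wm82.a2.v1, -3.15 for Glyma.15G272800.Wm82.a2.v1 and -2.78 for Glyma.03G036500.Wm82.a2.v1 (log2, young minus old). Of 100 splits of the libraries within leaf ages, drawn from 200, 6 gave at least 1320 genes, the real one included, a share that is not under 0.05. The highest of the other splits gave 11471 genes and exchanged the Mn labels of the young leaves. All 5 other splits as large kept the young-leaf Mn groups together and so carry the Mn response of young leaves, which points to a structure of the samples. The 82 splits with neither leaf age in its real grouping gave at most 2 genes. The splits therefore do not decide whether the count of the difference itself is due to chance.

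For the 4 comparisons of 3 against 3 libraries, 10 splits cannot give a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes. The real split gave 4551 genes for Mn in old leaves and the highest other split 1, and for Mn in young leaves 9957 and 0. For leaf age the counts were 12855 and 0 at 5 µM, and 11479 and 0 at 100 µM.

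The excess of higher calls in young leaves at high Mn goes with an upward shift of the median gene by 0.27 on the log2 scale. A few abundant genes taking fragments at 5 µM are a candidate source, but with library totals taken without the 20 most abundant genes the shift was still 0.229 (0.161 to 0.308 over the 9 pairs of libraries), which argues against those genes as its whole cause. The 1000 most abundant genes took 50.2 ± 1.4% of fragments at 5 µM and 42.6 ± 0.8% at 100 µM (SD, n = 3), and leaving them out left 0.118. FPKM is relative to the library total, so a falling share of these genes raises the others by arithmetic. The value thus describes a broad change of abundant transcripts and does not show what brought it about. Gene length as the cause cannot be told apart from a general shift: the median change went from 0.37 in the shortest to 0.17 in the longest sixth of genes, and in the longest it ran from 0.096 to 0.261 over pairs of libraries. A response of young leaves to Mn stays open, and FPKM without an added standard cannot show whether total transcript changed.

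Replicate 3 of the old-leaf 5 µM group stands apart: 2059 genes lie at least 2-fold from the mean of replicates 1 and 2, against 956 and 1278 for those replicates by the same measure. A wrong label within old leaves is argued against by its correlations across genes, with a median r of 0.947 with its own group and 0.915 with the 100 µM group, a difference of -0.032, and depth is argued against by replicate 1, whose total was 1.006 times that of replicate 3 and which deviates less. Across genes, its deviation correlates at r = 0.40 with the Mn response of young leaves, which rests on other libraries, and at 0.38 with trends of length and abundance removed; the 9 libraries of the other groups, each set against the response of the other leaf age, gave -0.27 to 0.21. Replicates 1 and 2 of its own group gave -0.14 and -0.34, but against means that include replicate 3, so that replicate 2 deviating the other way along the same axis stays open. Likeness of replicate 3 to old leaves at 100 µM was mixed. Its median r of 0.915 with that group lay below the 0.938 over all 9 pairs of libraries. On the third component it lay at -69.3, farther from that group (14.2 to 43.4) than replicates 1 and 2 (1.2 and -29.4). On the second it lay nearest, at -5.3 against -38.2 and -65.5. A candidate explanation is that this sample was partly in a state that high Mn also brings in young leaves. Whether Mn, leaf stage or stress brought it stays open, as none was measured in this sample.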

How the results depend on the processing

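The voom fit, the shared calls and the gap between leaf-age groups were added after seeing the data. Fold changes of the named genes were recomputed 440 times over 20 gene and comparison pairs, but not in fits on the 6 compared libraries alone. Of these values, 428 kept direction and call and 0 reversed. The other 12, all for the difference at Glyma.07G243500.Wm82.a2.v1, kept direction with adjusted p-values of 0.051 to 0.12. The cause of that loss was not tested beyond the spread of that gene. Counts within 1.5 times the main value under a setting are not listed here. The ranges over left-out libraries and the fit of young leaves alone are exceptions. Requiring a 2-fold change left 1497 genes for Mn in old leaves, 2696 for Mn in young leaves, 4717 for leaf age at 5 µM and 4472 at 100 µM, by construction. A mean FPKM of at least 5 tested 15650 genes and called 5680 for Mn in young leaves, 792 for the difference between leaf ages, 7506 and 6087 for leaf age at 5 and 100 µM, and 1489 for both leaf ages; fewer genes were tested. For the difference between leaf ages, quantile normalization gave 2037 and voom on recovered fragments 823, and the cause was not tested. Fitting the 6 old-leaf libraries alone gave 1038 genes, and fitting the 6 young-leaf libraries alone gave 13599. Both the variance and its degrees of freedom change in these fits. Degrees of freedom fall in both, so the rise in young leaves argues against them as the whole cause. The median SD between replicates was 0.266 in old leaves at 5 µM and 0.136 to 0.142 in the other groups, while the joint model gives all groups the same variance for a gene. Leaving out 1 library gave 2213 (without old-leaf 100 µM replicate 3) to 7537 (without old-leaf 5 µM replicate 3) for Mn in old leaves, 5253 (without young-leaf 5 µM replicate 3) to 13281 (without old-leaf 5 µM replicate 3) for Mn in young leaves, 194 to 3232 for the difference, 10117 to 13432 and 8934 to 14001 for leaf age at 5 and 100 µM, and 1312 to 4916 for both leaf ages. Pseudocounts of 0.1 and 5 moved no count by over 1.5 times. At 5, the log2 change of Glyma.17G147500.Wm82.a2.v1 in old leaves was 2.97 in place of 4.82. Depth of 17774122 to 21070730 fragments limits mainly genes of low FPKM.

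The replicate number as a replicate block gave 766 genes for the difference between leaf ages in place of 1320, moved no other count by over 1.5 times and ended, among named genes, the call of Glyma.07G243500.Wm82.a2.v1 (adjusted p = 0.06, 0.051 to 0.12 over the settings that lost it). Deviations from group means of libraries with the same number correlated at -0.47 to 0.26 across genes, and 3 of 12 libraries correlated best with their own number, so the numbers were not taken to pair the samples. The gene list tests, with an estimated correlation or fry, were not run, as no names were paired with the IDs.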

Other observations

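All tests in this part were chosen after the results were seen. Genes were grouped by the leaf age difference averaged over both Mn levels. In a balanced design this average shares no noise with the Mn contrasts if the groups vary equally. The median SD was 0.266 in old leaves at 5 µM and 0.141 at 100 µM, so that some noise is shared in old leaves. A low chance value in old leaves at 5 µM raises both the young minus old difference and the Mn change. Such noise would thus lift genes classed as higher in young leaves, opposite to the order of the medians below. With an adjusted p below 0.05 and a difference of at least 2-fold, 2478 genes were higher in young leaves and 1571 higher in old leaves. The median change with Mn differed between these groups in both leaf ages. In old leaves the genes higher in old leaves had a median log2 change of 0.29, against 0.09 for all genes, and the genes higher in young leaves -0.04. In young leaves the medians were 0.44 for genes higher in old leaves, 0.27 for all genes and 0.05 for genes higher in young leaves. Relative to all genes, the genes higher in old leaves thus moved by 0.20 and 0.18 and the genes higher in young leaves by -0.13 and -0.22, in old and young leaves respectively. In young leaves 39.1% of the genes higher in old leaves were called higher with Mn and 5.3% lower; after median-of-ratios rescaling these were 27.8% and 8.8%. Of the genes higher in young leaves 18.5% were called higher with Mn and 13% lower, and after rescaling 10% and 25.5%. Among the 24218 genes in neither group the shares in young leaves were 30.2% higher and 4.8% lower, and after rescaling 11.2% and 11.7%. The 5.3% of lower calls among genes higher in old leaves was therefore near that of the other genes.

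The gap between the groups was 0.33 in old leaves and 0.39 in young leaves, with a mean of 0.363. Of the 200 splits of the libraries within leaf ages, 2 gave a mean this large, the real one included, a share under 0.05. The real split was not the highest, since the other gave 0.408. For either leaf age alone 10 splits cannot give a share under 0.05, and in young leaves another split gave 0.485, above the real 0.39. A difference in abundance between the groups is argued against as the whole cause, since the gap remained within 6 classes of abundance. It averaged 0.387 in young leaves (95% bootstrap interval over genes 0.337 to 0.438) and 0.394 in old leaves (0.347 to 0.44). These intervals treat genes as independent and leave out the spread between libraries, so they do not test the gap itself. The gap in young leaves still varied with abundance, at 0.061 and 0.164 in the 2 lowest classes and 0.47 to 0.595 in the upper 4, while in old leaves it ran from 0.261 to 0.486. The gap kept its sign in all 44 recomputed values, from 0.223 to 0.458 in old leaves and 0.176 to 0.636 in young leaves. What brings the gap about was not tested beyond this, and Mn itself, growth rate and the share of cell types stay open, as no markers could be named.

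Genes with the same response followed each other in the order of gene IDs within chromosomes, which stands in here for position, more often than in permuted orders for 5 of 6 sets. Among genes called lower with Mn in old leaves, 158 neighbouring pairs were found, against a mean of 78.5 and a highest value of 107 in 1000 permutations (adjusted p = 0.001 over 6 tests, the smallest they can give). Young leaves gave 143 pairs of lower genes against 87.9, and higher genes gave 427 against 328 in old and 2766 against 2467 in young leaves, each with an adjusted permutation p of 0.001. Genes with a more positive response in young than in old leaves gave 77 pairs against 39.3 (adjusted permutation p = 0.001), and those with a more negative response 3 against 2.2 (adjusted permutation p = 0.4). The order of IDs thus carries information on the response in those 5 sets, and tandem copies that respond alike, or that share fragments, may be a reason that was not tested.

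A few genes went from near absence to expression. In young leaves 16 genes had at most 3 fragments over the 3 libraries at 5 µM and an FPKM of at least 1 in each library at 100 µM, and 1 gene did the reverse. In old leaves 2 and 1 genes did so. Between leaf ages, 146 genes near absence in old leaves were expressed in young leaves at 5 µM and 19 the reverse, and at 100 µM the numbers were 183 and 15.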
